A study of Arabidopsis thaliana with 8 samples.

How the data were processed

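RNA from whole Arabidopsis thaliana plants of the Col-0 accession was measured on 8 one-colour Affymetrix ATH1 arrays with biotin-labelled targets. Per the labels, plants grew on agar plates at 24 °C under continuous light of about 100 µmol per square metre per second and were 10 days old at the start of treatment, after 4 days of cold stratification of the seed. The cold samples were then kept at 4 °C for 1 h, 24 h or 7 days under about 25 µmol per square metre per second. The 0 h samples were harvested under the growth conditions. Each of the 4 groups holds 2 arrays, numbered 1 and 2 in the labels. Cold plants differed from the 0 h plants in temperature and in light, and at 7 days also in age. No plants kept warm for 24 h or 7 days were analysed here.

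The deposited values are signal intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal. Its version, its settings and any detection calls are not given in the sources used here. The values themselves show the authors' scaling: the mean signal of each array without the lowest and highest 2% of probe sets was between 99.95 and 99.96. No further normalization was applied to the main values. The median signal over all probe sets and arrays was 40.9.

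The table holds 22810 probe sets, of which 64 are control probe sets that were left out of the tests. Genes were named through the platform's probe annotation, updated by gene identifier with a RefSeq gene table of assembly TAIR10.1 used for names only. A single gene was paired with 13513 probe sets, of which 13436 matched the gene table and 77 kept the symbol of the probe annotation. Another 503 pair with several genes and were not named, and 8730 are not listed in the annotation used here and stay unnamed. Genes known only by a locus code are better covered than genes with a symbol: 63.1% of the first and 14.6% of the second were paired. Many familiar cold-response genes, among them CBF1, CBF2, CBF3, RD29A, CCA1 and LHY, are therefore not analysed here by name. A gene with several probe sets is represented by the one with the highest mean. Among 85 genes with several tested probe sets, opposite calls occurred for 1 gene at 7 days and for 0 genes in the other comparisons. Calls in only some probe sets of a gene were more frequent. They occurred for 0 of these genes at 1 h, 20 at 24 h, 16 at 7 days, 14 for 24 h against 1 h and 9 for 7 days against 24 h.

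Signals were transformed as log2(signal + 8), where 8 is 20% of the median signal rounded to a whole number. Fold changes are on this scale, which understates the change of dim genes. A probe set was tested if its signal lay above the 40th percentile of its array on at least 2 arrays, which 15017 did. These comprise 8125 probe sets of 1 gene, 289 of several genes and 6603 unlisted ones, and they cover 8033 named genes. One limma model with a mean per group was fitted to all 8 arrays with 4 residual degrees of freedom, and variances were moderated with an intensity trend (prior degrees of freedom 7.67). The 5 contrasts were each cold time against 0 h, 24 h against 1 h, and 7 days against 24 h. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 15017 probe sets, with calls at an adjusted p under 0.05. A moderated F test over the 3 contrasts against 0 h asked which probe sets differed at any time. Nothing in the labels says that arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision; the median standard error of a log2 fold change was 0.24.

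Gene groups were tested with limma's camera at a preset correlation of 0.01, where at least 5 members were tested, and counts were given for smaller groups. The design, the test settings, 19 gene lists and the rule for named genes were fixed before the data were examined. Of the 332 entries in these lists, 38 were measured by a probe set of their own and 287 have no probe set paired with them. Only the lists of cold-regulated (COR) genes, nuclear photosynthesis genes and auxin and growth genes had at least 5 tested members, so camera tested no other fixed list. A further 26 lists were drawn from the gene symbols after the annotation had been seen and before any fold change, and their p-values were adjusted separately. With the correlation estimated from the data in place of the preset one, camera called none of the lists, fixed or drawn later, in any comparison. The rule for named genes takes the 10 largest rises and the 10 largest falls against 0 h among called, single-gene probe sets whose arrays do not overlap between the groups. It takes 5 each way between cold times, up to 4 called members of each fixed list, and COR15A, COR15B and COR47 whatever their result. Other members of the later lists named in the text, beyond those taken by this rule or on a fixed list, were chosen after their values were seen. They came from those whose call held with each array left out in turn. JAL34 is an exception, named with the genes of endoplasmic reticulum bodies although its call did not hold.

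Overlaps between times share the 0 h arrays, so unchanged groups against those arrays were simulated 100 times. The fit was tested on simulated data for the 24 h comparison, with 200 of 15017 probe sets changed in each of 20 simulations. It recovered 2.8%, 48.9%, 98.4% and 100% of log2 changes of 0.5, 1, 2 and 3, and 7.2% of its calls were false. Of unchanged gene lists, 1.2% had a p under 0.05, with genes simulated as independent of each other. This rate therefore does not cover lists whose members vary together.

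The alternatives were other pseudocounts (2 and 24), quantile normalization, scaling to equal medians, no filter or a stricter one, other variance priors, fits of 4 arrays, the replicate number as a block, a 2-fold minimum, and leaving out each array. When an array is left out, the lone array of its group is assumed to vary like the others. A planned search for promoter motifs was not run, because no genome sequence was used here. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3.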

Results

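Transcript levels were measured in whole 10-day-old Arabidopsis plants, accession Col-0, before cold treatment (0 h) and after 1 h, 24 h and 7 days at 4 °C, with 2 arrays per group. Values are MAS5 signals, in which each array's trimmed mean is set near 100, and means are given with the SD over 2 arrays. Replicate arrays correlated at r = 0.961 (0 h), 0.972 (1 h), 0.956 (24 h) and 0.966 (7 days) across 15017 probe sets, which are not independent replicates. Between 1.4% (1 h) and 3.5% (24 h) of probe sets differed by over 2-fold between the arrays of a group. The first principal component held 55.8% of the variance and placed the 0 h and 1 h arrays apart from the 24 h and 7-day arrays. The second separated 24 h from 7 days, with scores of -26.6 and -28 against 38.4 and 30.8. The ratio of 3' to 5' signal of the actin control probe sets, a measure of RNA integrity and labelling, ranged from 2.95 at 0 h (replicate 2) to 6.53 at 24 h (replicate 1). At 1 h it was 5.32 and 3.95, at 0 h 3.84 and 2.95, and at 7 days 3.83 and 5.91. The same ratio ranged from 1.22 to 1.45 for GAPDH and from 1.81 to 2.85 for ubiquitin. Neither measured reference gene passed the test at 24 h: PEX4, a ubiquitin-conjugating enzyme gene, was at a log2 fold change of 0.40 at 24 h (adjusted p = 0.119) and AT2G28390 at 0.20 (adjusted p = 0.479).

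**Figure D1:**
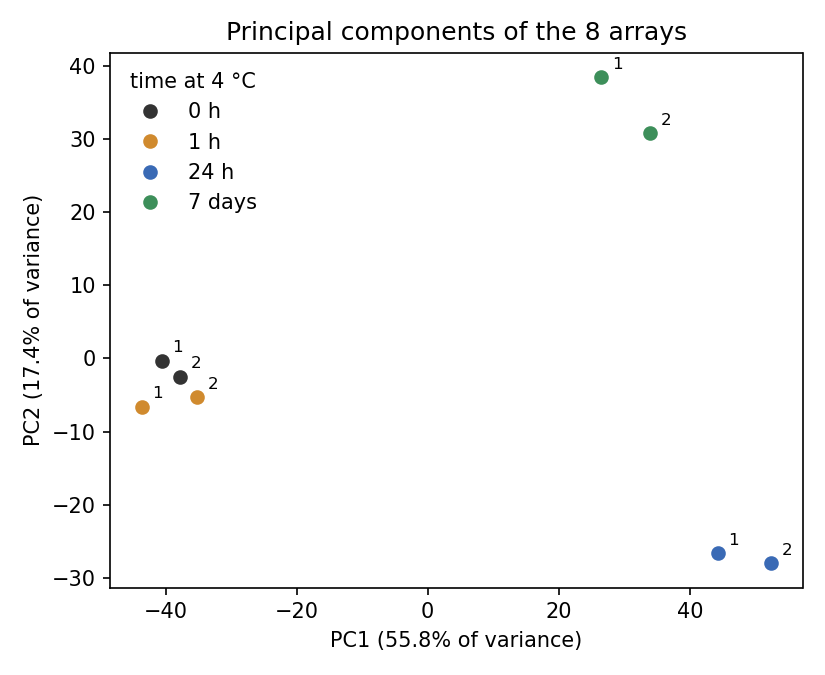
Scores of the 8 arrays on the first and second principal components of log2(signal + 8) over 15017 probe sets, with points coloured by time at 4 °C and numbered by replicate. The 0 h and 1 h arrays lie at negative scores on the first component (55.8% of the variance), and the second parts 24 h (-26.6 and -28) from 7 days (38.4 and 30.8).

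Which transcripts respond within the first hour was asked by comparing 1 h with 0 h. Few passed the test, and nearly all of those were higher. STZ, a zinc finger repressor of stress signalling also called ZAT10, rose from a signal of 34.8 ± 9.04 to 416 ± 57.8 (SD, n = 2), a log2 fold change of 3.32 ± 0.22 (SE, limma adjusted p = 3.18e-05). AT3G04640 rose by 2.28 ± 0.23 (adjusted p = 0.000665) and AT1G25550 by 1.76 ± 0.17 (adjusted p = 0.000665). The cold-regulated genes COR15A, COR15B and COR47, whose products protect chloroplasts and membranes during freezing, did not pass the test at this time, with log2 fold changes of 0.44, 0.64 and -0.22 (adjusted p = 1 for each).

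In all, 47 probe sets rose and 1 fell at 1 h, each by at least 2-fold, and 685 had an unadjusted p under 0.05. Smaller changes at this time may therefore have gone uncalled. The arrays of both groups did not overlap for 32.4% of probe sets, where chance gives 33.3%. Of these 48 calls, 16 were of named genes, all higher, and 31 risers were unlisted probe sets. The count was 23 without 0 h replicate 1, 16 without 0 h replicate 2, 18 without 1 h replicate 2, 23 without the filter on dim probe sets and 29 without the intensity trend. A pair of unnamed probe sets rose more than STZ, by 3.54 (adjusted p = 1.22e-05) and 3.49 (adjusted p = 0.000188). The other genes among the 10 largest rises of named genes were AT2G20670 (1.79, adjusted p = 0.0181), AT1G32920 (1.75, adjusted p = 0.00439), AT4G27280, an EF-hand calcium-binding protein gene (1.71, adjusted p = 0.00443), AT1G25400 (1.69, adjusted p = 0.0222), AT4G29780 (1.68, adjusted p = 0.0188), AT1G76600 (1.56, adjusted p = 0.00901) and AT5G50450 (1.45, adjusted p = 0.0219). These 7 calls were not kept with every array. Leaving out 0 h replicate 1 ended 5 of them (adjusted p 0.0601 to 0.171), 0 h replicate 2 ended 7 (0.0527 to 0.129), 1 h replicate 1 ended 3 (0.0522 to 0.184) and 1 h replicate 2 ended 7 (0.0562 to 0.289). STZ, AT3G04640 and AT1G25550 were called with each array left out.

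Among the gene lists, the first-wave transcription factors were represented by STZ alone, which rose (1 of 1). Adjustment over a list with 1 tested gene leaves the p-value unadjusted, so it adds nothing to that call. None of the 6 measured COR genes passed the test (0 of 6 adjusted over the list alone, 1 at an unadjusted p under 0.05), and the list's median log2 change was 0.54 (camera adjusted p = 0.192). That value depended on 1 array: without 1 h replicate 1 the median was 1.09 (adjusted p = 8.54e-07). The arrays at 1 h differed, with COR15A signals of 10.1 and 104, COR15B of 48 and 157, and COR27 of 50.5 and 266 in replicates 1 and 2. WRKY53, a transcription factor gene on the list of calcium- and touch-responsive genes, had a log2 fold change of 1.21 (adjusted p = 0.0875). It was the only gene tested of that list, so its pass adjusted over the list alone means only an unadjusted p under 0.05. Of the 6 nuclear photosynthesis genes 0 passed, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their median was 0.16 (camera adjusted p = 0.192), -0.04 after quantile normalization, and 0.45 without 0 h replicate 2 (adjusted p = 0.000252). The 6 auxin and growth genes likewise gave 0 calls, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.709).

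On the lists drawn from the annotation, rapid stress signalling genes were higher as a group at 1 h (median 0.41, camera adjusted p = 8.64e-09, but adjusted p = 0.202 with an estimated correlation), with STZ the 1 called member of 12. Chloroplast-encoded transcripts were also higher as groups. The median was 0.66 for 33 genes of the photosynthetic complexes (camera adjusted p = 1.37e-20), 0.97 for 9 ndh genes (adjusted p = 7.03e-13) and 0.63 for 19 genes of plastid transcription and translation (adjusted p = 7.29e-10). With an estimated correlation these were adjusted p = 0.202, adjusted p = 0.202 and adjusted p = 0.22. Without 1 h replicate 1 the medians were 0.37, 0.46 and 0.31 (adjusted p = 6.69e-06, 1.96e-05 and 0.0232), and without 1 h replicate 2 that of the ndh genes was 1.52. No single chloroplast-encoded gene was called: 0 of 68 passed and 36 had an unadjusted p under 0.05. Their mean log2 signal was 8.26 and 8.27 on the 0 h arrays but 9.32 and 8.63 on the 1 h arrays, where the actin ratios were 5.32 and 3.95. Glutathione transferase genes were lower as a group (10 tested, 0 called and 0 at an unadjusted p under 0.05, median -0.32, adjusted p = 0.0133, but adjusted p = 0.22 with an estimated correlation). Their call was lost without 0 h replicate 1 (median -0.19, adjusted p = 0.443) or 1 h replicate 2 (adjusted p = 0.123). The 33 nuclear-encoded photosynthesis genes had a median of 0.08 (camera adjusted p = 0.648, and 0.029 without 0 h replicate 2, where the median was 0.16).

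**Figure D2:**
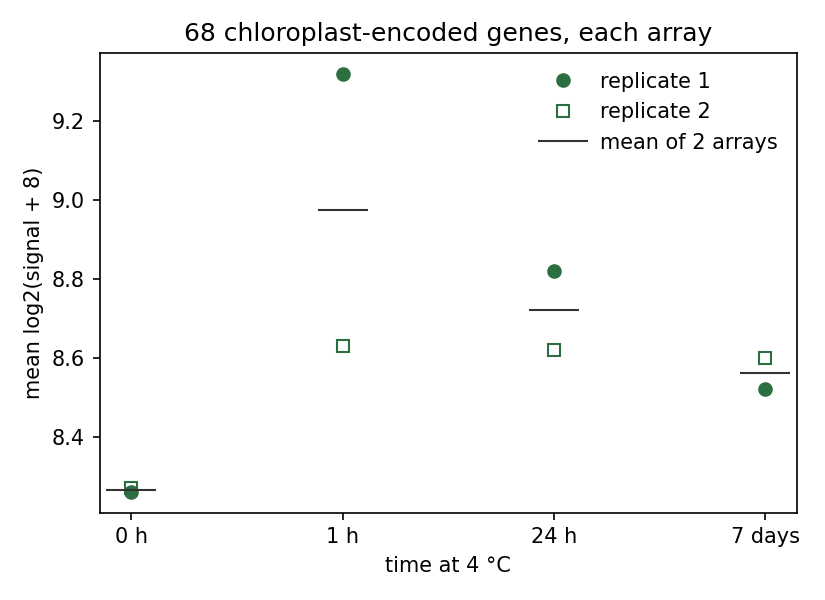
Mean log2(signal + 8) of 68 chloroplast-encoded genes on each array, by time at 4 °C; filled and open symbols are replicates 1 and 2, and dashes the mean of 2 arrays. The 1 h arrays lie at 9.32 and 8.63, above the 0 h arrays at 8.26 and 8.27.

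What a day of cold changes was asked by comparing 24 h with 0 h, and the cold-regulated genes rose strongly. COR15A rose from 25.7 ± 8.44 to 6140 ± 2290 (SD, n = 2), a log2 fold change of 7.48 ± 0.60 (SE, limma adjusted p = 1.42e-05). COR15B rose by 5.83 ± 0.41 (adjusted p = 6.39e-06) and the dehydrin genes LTI30 and COR47 by 5.27 ± 0.29 (adjusted p = 1.07e-06) and 3.12 ± 0.28 (adjusted p = 2.42e-05). NRPA1, a subunit gene of RNA polymerase I, rose by 1.77 (adjusted p = 0.000123), while the autophagy gene ATG8H fell by 2.08 (adjusted p = 0.00736) and the leucine breakdown gene MCCA by 2.35 (adjusted p = 0.00109). The circadian clock gene GI (GIGANTEA) rose by 2.76 ± 0.43 (adjusted p = 0.000788).

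**Figure D3:**
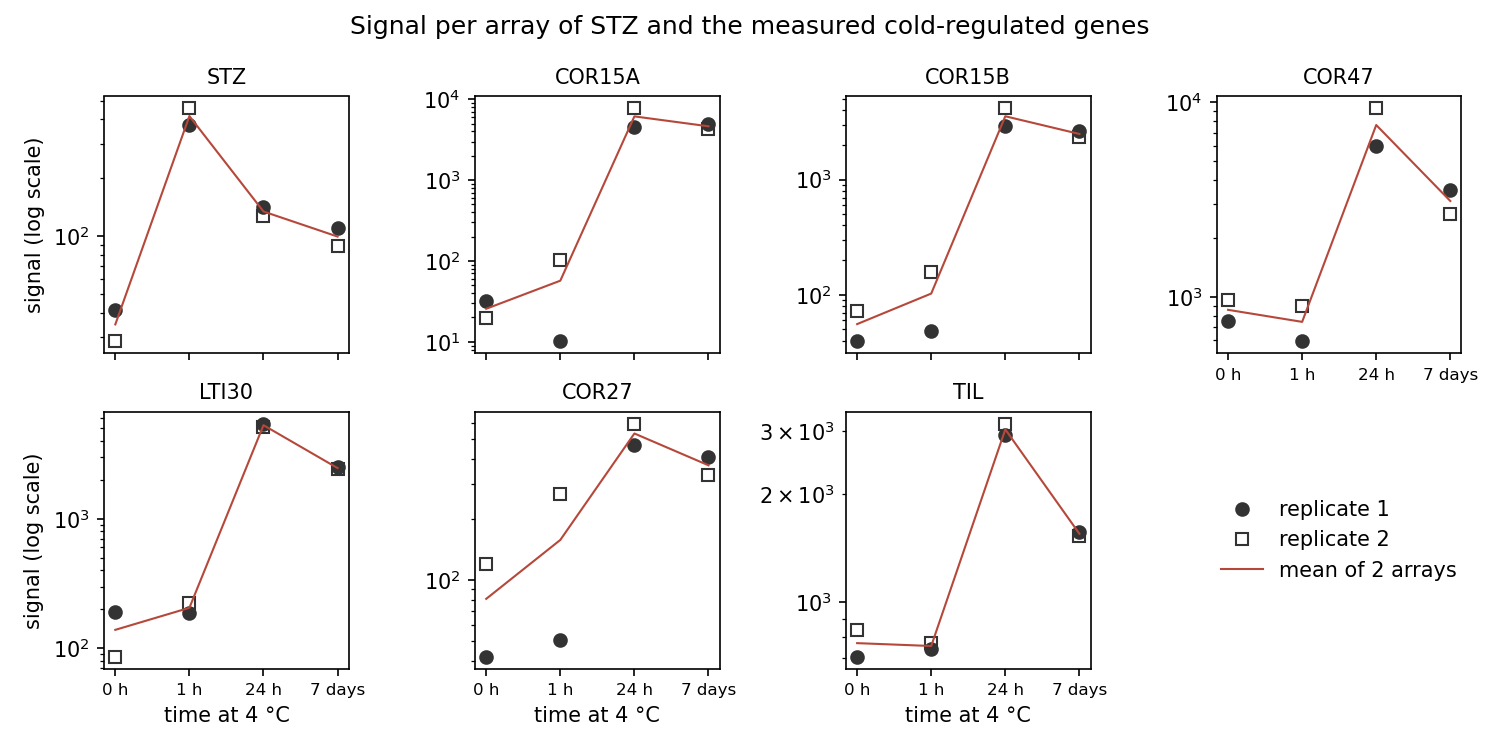
MAS5 signal per array (log scale) of STZ and the 6 measured cold-regulated genes against time at 4 °C, with filled and open symbols for replicates 1 and 2 and a line through the means. STZ is highest at 1 h (416 against 34.8 at 0 h), and COR15A rises from 25.7 at 0 h to 6140 at 24 h and 4630 at 7 days.

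At 24 h, 1771 probe sets rose and 2303 fell, which is 27.1% of those tested, and 975 and 1124 of these changed at least 2-fold. The named genes among them were 921 that rose and 1215 that fell. The total of 4074 was 2694 without 0 h replicate 1 and 2705 without 24 h replicate 2. The direction of the majority depended on scaling: 43.5% of calls were higher, but 53.5% (2047 higher, 1776 lower) when arrays were scaled to equal medians. Groups did not overlap for 61.3% of probe sets, again against 33.3% by chance.

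The largest rises of named genes at 24 h included AT1G16850 (log2 fold change 6.66, from 1.86 to 989), AT1G80130 (4.73), AT3G55580, an RCC1-like repeat gene (4.53), AT1G51090 (3.96), AT1G11210 (3.83), EXLA2, an expansin-like gene (3.80), and AT2G16890 (3.55), with adjusted p from 3.46e-08 to 0.000889. The largest falls were AT2G05540 (-4.43, from 919 to 34.9), AT4G27450 (-3.84), AT3G28270 (-3.63), AT4G39675 (-3.55), AT4G33666 (-3.50), AT1G51400 (-3.44), AT4G33660 (-3.36), AT5G14120 (-3.34), the expansin gene EXPA8 (-3.25) and AT1G23390 (-3.24), with adjusted p from 3.16e-06 to 0.000265. Of unnamed probe sets, the largest rises were 6.46 (adjusted p = 4.09e-07) and 6.25 (adjusted p = 5.69e-07), and the largest falls -4.03 (adjusted p = 5.4e-05) and -3.97 (adjusted p = 2.54e-05). All of these calls of named genes were kept with each array left out.

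All 6 measured COR genes rose at 24 h, 6 of 6 also adjusted over the list alone, with a median of 4.19. Besides those above they were COR27 (2.75, adjusted p = 0.00449) and the temperature-induced lipocalin gene TIL (1.97, adjusted p = 2.78e-05). The list's camera adjusted p was 4.02e-09, and adjusted p = 0.0666 with an estimated correlation. STZ was still above 0 h, by 1.74 (adjusted p = 0.000188). Of 4 flavonoid genes 2 rose (2 adjusted over the list alone): UGT78D2, a flavonoid glucosyltransferase (2.00, adjusted p = 0.000359), and AT5MAT, an anthocyanin malonyltransferase (1.04, adjusted p = 0.0286). The AT5MAT call was lost without 0 h replicate 1 (adjusted p = 0.101), 0 h replicate 2 (0.0772), 24 h replicate 2 (0.211) or the filter (0.0696). GSTU25, a glutathione transferase gene, rose by 1.94 (adjusted p = 0.00128) and PRH75, an RNA helicase gene, by 0.97 (adjusted p = 0.00441). Each was the only tested gene of its list, so adjustment over the list alone leaves its p-value unadjusted and adds no support.

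The 6 auxin and growth genes went both ways at 24 h. IAA29, an auxin-response repressor gene (2.34, adjusted p = 0.000945), and GH3.3, an auxin-conjugating enzyme gene (1.56, adjusted p = 0.00195), rose, and EXPA8 and EXPA4 fell. Adjusted over the list alone 3 rose and 2 fell, and camera gave an adjusted p of 0.447. EXPA4 (-0.89, adjusted p = 0.0161) was no longer called without 0 h replicate 1 (adjusted p = 0.124) or 24 h replicate 1 (0.0919). Of 6 nuclear photosynthesis genes 1 fell (1 adjusted over the list alone), the light-harvesting gene LHCB4.2 (-1.02, adjusted p = 0.0078). Its call was lost without 0 h replicate 2 (adjusted p = 0.0521) or 24 h replicate 1 (0.059). The list's median was -0.10 (camera adjusted p = 0.447), -0.39 with 4 genes lower after quantile normalization (adjusted p = 0.00519), and -0.41 without 0 h replicate 1 (adjusted p = 0.0461). Of 3 root genes 1 fell (1 adjusted over the list alone), PYK10, a beta-glucosidase of endoplasmic reticulum bodies (-0.81, adjusted p = 0.0406), and EXPA7 and EXPA18 were at -0.16 and 0.27 (adjusted p = 0.72 and 0.53). The PYK10 call was lost without 0 h replicate 1 (0.132), 0 h replicate 2 (0.0792), 1 h replicate 1 (0.0518), 1 h replicate 2 (0.052) or 24 h replicate 2 (0.331), and with equal medians (0.0937), no filter (0.0915), no intensity trend (0.064) or 4 arrays (0.0645), while without 24 h replicate 1 it was called at -1.24. AT5G48570, the 1 heat shock gene tested, stood at -1.17 (adjusted p = 0.0649). Its call adjusted over the list alone means only an unadjusted p under 0.05.

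Among the lists drawn from the annotation, 15 of 34 genes of RNA processing and RNA polymerases rose at 24 h and 1 fell (median 0.58, camera adjusted p = 7.64e-06, but adjusted p = 0.346 with an estimated correlation). They included YAO (2.02), ATL5 (1.95), NRPA1 and NRPA2, the large subunits of RNA polymerase I (1.77 and 1.32), and IMP4 (1.45). Of 13 dehydration-related genes 8 rose and 1 fell (median 1.89, adjusted p = 0.000133, and adjusted p = 0.416 with an estimated correlation), but this list holds all 6 measured COR genes. Of its 7 other genes 2 rose, among them RD2 (1.71), and 1 fell, with a median of 0.09. Of 10 autophagy genes 7 fell (median -1.04, adjusted p = 0.000425, and adjusted p = 0.416 with an estimated correlation). ATG8H was at -2.08, ATG8F at -1.97 and ATG8E at -1.53, all members of the ATG8 family that coats autophagosomes. Of 9 genes of amino acid breakdown 7 fell (median -1.11, adjusted p = 0.00681, and adjusted p = 0.416 with an estimated correlation), including MCCA (-2.35), MCCB (-1.67) and IVD (-1.11) of leucine breakdown. The camera calls of these 4 lists held with each array left out.

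The median of the nuclear-encoded photosynthesis genes lay below 0 h at 24 h and that of the chloroplast-encoded ones above, a difference that was not itself tested. Of 33 nuclear genes, which include the 6 above, 11 fell (median -0.31, camera adjusted p = 0.0267, but adjusted p = 0.556 with an estimated correlation), among them PGRL1B of cyclic electron flow (-1.55), NdhN (-1.06) and the chlorophyll synthesis gene CHLM (-0.93). That list's call was lost without 0 h replicate 2 (median -0.17, adjusted p = 0.165) or 24 h replicate 1 (0.118). Of 33 chloroplast genes 6 rose (median 0.59, adjusted p = 0.00681, but adjusted p = 0.56 with an estimated correlation), led by rbcL, the large subunit of Rubisco (2.26, adjusted p = 0.00224), and of 9 ndh genes 4 rose (adjusted p = 0.0267, but adjusted p = 0.56 with an estimated correlation). The chloroplast calls were lost after quantile normalization (adjusted p = 0.059 for both) and without 24 h replicate 1 (0.109 and 0.118), and the ndh call also without 0 h replicate 1 (0.0566), where the median of the 33 chloroplast genes was 0.31. The 19 chloroplast genes of transcription and translation did not pass as a list at 24 h with all arrays. Their median was 0.43 with 4 rises after quantile normalization. It was 0.59 without 0 h replicate 1 and 0.55 without 24 h replicate 2, and the list passed with either of these arrays left out. Actin 3' to 5' ratios at 24 h were 6.53 and 3.44, and the mean log2 signals of the 68 chloroplast genes were 8.82 and 8.62.

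**Figure D4:**
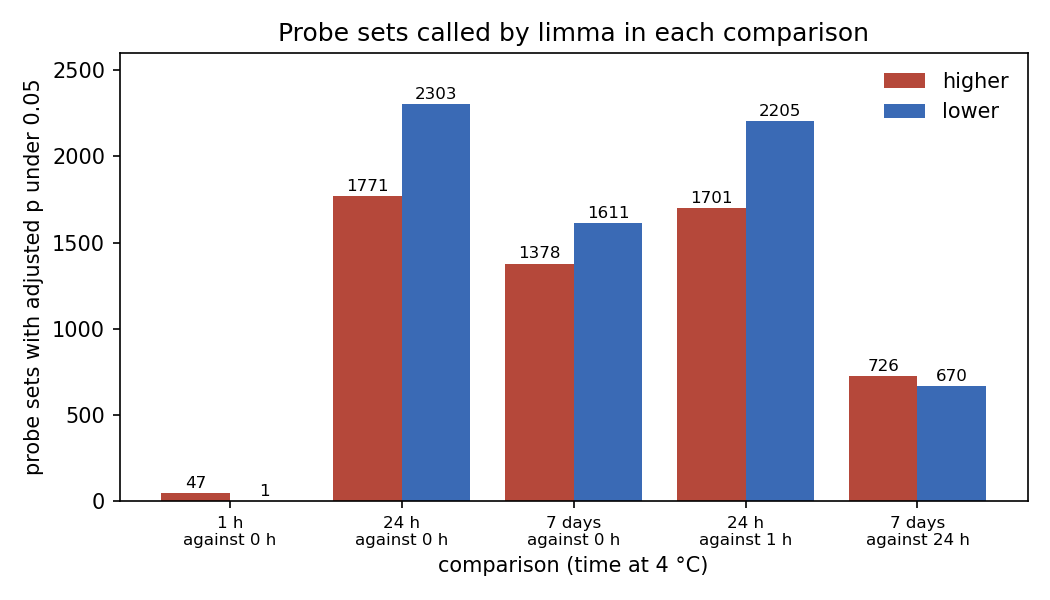
Number of probe sets called higher (red) and lower (blue) by limma at an adjusted p under 0.05 in each of 5 comparisons, of 15017 tested. Calls at 1 h number 47 and 1, against 1771 and 2303 at 24 h and 1378 and 1611 at 7 days.

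Which changes are present after a week was asked by comparing 7 days with 0 h, and the COR genes were again high. COR15A stood at 4630 ± 444 (SD, n = 2), a log2 fold change of 7.13 ± 0.60 (SE, limma adjusted p = 2.92e-05), and COR15B at 5.35 ± 0.41 (adjusted p = 1.6e-05). LTI30 was higher by 4.17 ± 0.29 (adjusted p = 7.34e-06) and COR47 by 1.85 ± 0.28 (adjusted p = 0.00105). The plant defensin gene PDF2.1 rose by 3.91 ± 0.31 (adjusted p = 1.6e-05) and XTH20, a xyloglucan-modifying enzyme of the cell wall, by 3.55 ± 0.28 (adjusted p = 1.91e-05). PYK10 fell by 1.40 on the log2 scale (adjusted p = 0.00386).

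At 7 days 1378 probe sets rose and 1611 fell, 19.9% of those tested, of which 659 and 813 changed at least 2-fold. Named genes made up 738 of the rises and 798 of the falls. The total of 2989 was 1826 without 0 h replicate 1, 1890 without 0 h replicate 2, 1970 without 7-day replicate 1 and 1472 without 7-day replicate 2. Of the calls 46.1% were higher, but 58.4% (1655 higher, 1179 lower) with arrays scaled to equal medians. Groups did not overlap for 59.9% of probe sets, where chance gives 33.3%.

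Other large rises at 7 days were AT1G16850 (log2 fold change 4.80), AT1G80130 (4.76), AT3G55580 (4.26), AT4G12490 (3.58) and AT4G30650, a gene of the RCI2 family of small membrane proteins (3.27), with adjusted p from 4.79e-07 to 0.000192. The largest falls were AT4G21870, a small heat shock protein-like gene (-4.21, from 294 to 9.62), AT2G05540 (-3.54), AT3G28270 (-3.41), AT1G04350 (-3.29), AT3G24100 (-3.27), AT4G27450 (-3.13), AT4G33666 (-2.88), AT4G39675 (-2.86), AT2G27420 (-2.81) and AT1G68440 (-2.78), with adjusted p from 4.98e-06 to 0.00133. Among unnamed probe sets the largest rises were 5.42 (adjusted p = 4.79e-07) and 5.33 (adjusted p = 2.14e-06), and the largest falls -4.80 (adjusted p = 6.18e-07) and -4.54 (adjusted p = 4.37e-06). The named calls in both sets of 10 were kept with each array left out.

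All 6 measured COR genes were again higher (6 of 6 adjusted over the list alone, median 3.20, camera adjusted p = 1.41e-08, and adjusted p = 0.0744 with an estimated correlation). TIL was at 1.01 (adjusted p = 0.0026) and COR27 at 2.24 (adjusted p = 0.0177). STZ (1.33, adjusted p = 0.00165), IAA29 (2.05, adjusted p = 0.0032), GI (2.1, adjusted p = 0.00588), GSTU25 (1.47, adjusted p = 0.00891) and WRKY53 (0.96, adjusted p = 0.019) were also higher, and EXPA8 was lower (-1.55, adjusted p = 0.0166). STZ, GI, GSTU25 and WRKY53 were each the only tested gene of a list, so adjustment over that list alone leaves their p-values unadjusted. The auxin and growth list gave 1 rise and 1 fall of 6, the same counts adjusted over the list alone (camera adjusted p = 0.822), and the root list 1 fall of 3 (1 adjusted over the list alone). Leaving out 7-day replicate 2 ended the calls of COR27 (adjusted p = 0.0771), EXPA8 (0.149), GI (0.0529), GSTU25 (0.0633) and WRKY53 (0.117). Without 7-day replicate 1 COR27 (0.0981) and WRKY53 (0.0563) were lost. Without 0 h replicate 1 COR27 was lost (0.122) and GI was at 1.32 (adjusted p = 0.033), without 0 h replicate 2 EXPA8 (0.125), GSTU25 (0.0551) and WRKY53 (0.11), and without the filter COR27 (0.0534). Of 4 flavonoid genes and 6 nuclear photosynthesis genes 0 were called, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The photosynthesis list's median was -0.03 (camera adjusted p = 0.822), 0.08 with equal medians, and -0.43 with 5 genes lower after quantile normalization (adjusted p = 0.00142).

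Of 34 genes of RNA processing and RNA polymerases, 10 were higher at 7 days and 1 was lower (median 0.34, camera adjusted p = 0.000512, but adjusted p = 0.546 with an estimated correlation), including NRPB7 (1.23), RH39 (1.21) and PGY1, a ribosomal protein gene (1.16). Of 13 dehydration-related genes 7 rose and 3 fell (median 1.01, adjusted p = 0.013, but adjusted p = 0.546 with an estimated correlation, and 0.0752 without 7-day replicate 1). Of the 7 that are not COR genes 1 rose, RD2 (1.11), and 3 fell, with a median of -0.21. Of 10 autophagy genes 2 fell (median -0.48, adjusted p = 0.0171, but adjusted p = 0.546 with an estimated correlation), with ATG8F at -1.12. The autophagy call was lost without 0 h replicate 1 (0.0777) or 7-day replicate 2 (0.0538). Of 19 chloroplast genes of transcription and translation 5 rose (median 0.54, adjusted p = 0.0158, but adjusted p = 0.546 with an estimated correlation), with rpoC2 at 1.80. The 33 chloroplast genes of the photosynthetic complexes (1 rose, median 0.15, -0.03 after quantile normalization, adjusted p = 0.566) and the 9 ndh genes (0 called, 2 at an unadjusted p under 0.05, median 0.09, adjusted p = 0.457) did not pass. The call of the 19 genes was lost without 0 h replicate 2 (median 0.21, adjusted p = 0.217) or 7-day replicate 2 (median 0.25, adjusted p = 0.065). The list of 26 UDP-glycosyltransferase genes, with 1 rise and 4 falls, had a median of -0.51 (adjusted p = 0.0463, but adjusted p = 0.559 with an estimated correlation). That call was lost without 0 h replicate 1 (0.255), 1 h replicate 1 (0.0551), 1 h replicate 2 (0.0566), 7-day replicate 2 (0.112) or the filter (0.166), and after quantile normalization (0.06). The 7-day arrays had actin ratios of 3.83 and 5.91. Nuclear photosynthesis genes at 7 days included PGRL1B (-1.95), NdhN (-1.39) and LHCB4.3 (-2.59), which fell, and the chlorophyll synthesis gene CHLI2 (1.29), which rose. That list of 33 had a camera adjusted p of 0.309, and 0.000745 after quantile normalization (median -0.43).

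How far the changes at different times coincide was asked from the calls against 0 h. At 24 h and 7 days 817 probe sets rose in both and 1066 fell in both, where independent lists would share 162.5 and 247.1, and 22 changed in opposite directions. Their fold changes correlated at r = 0.73 across probe sets, where simulated unchanged groups that share simulated 0 h arrays gave 0.5. The covariance was 0.363 against 0.034, a difference of 0.329. Part of the excess in shared calls over independent lists may come from the shared 0 h arrays, which are too few to divide between the comparisons. The simulated overlap of calls was 0, but no probe set was changed there, so few calls could arise. This 0 does not measure what the shared arrays add among probe sets that changed. The overlap of 1883 probe sets was 1106 without 0 h replicate 1, 1176 without 0 h replicate 2 and 1023 without 7-day replicate 2, values added after the data had been seen. Of the 47 probe sets higher at 1 h, 16 were higher and 10 lower at 24 h than at 0 h, 12 were higher at 7 days, and 34 were lower at 24 h than at 1 h. The 47 were picked by their 1 h arrays, which the last comparison uses again, so noise on those arrays favours a fall. The 16 shared rises compare with 5.5 for independent lists and were 8 without 0 h replicate 1, 8 without 0 h replicate 2 and 10 without 1 h replicate 2. Fold changes at 1 h and 24 h correlated at r = 0.22, below the 0.5 that shared 0 h arrays alone gave, with a covariance of 0.049 against 0.034. The 12 compare with 4.3 and were 5, 5 and 6 without the same arrays, with r = 0.19 against 0.5 and a covariance of 0.037 against 0.034. Across the 3 times, 4980 probe sets (33.2%) passed the F test.

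The comparison of 24 h with 1 h asked what changed between early and later cold. COR15A rose by 7.04 ± 0.60 on the log2 scale (limma adjusted p = 1.78e-05), AT1G16850 by 6.30 (adjusted p = 6.52e-08), COR15B by 5.19 (adjusted p = 1.18e-05), LTI30 by 4.63 (adjusted p = 2.42e-06), AT1G80130 by 4.42 (adjusted p = 5.53e-07) and COR47 by 3.34 (adjusted p = 1.35e-05). STZ fell from 416 to 134 (-1.58 ± 0.22, adjusted p = 0.000327) and WRKY53 from 62.6 to 21 (-1.28, adjusted p = 0.00301). The largest falls were AT2G05540 (-4.19), AT4G27450 (-3.94), AT5G14120 (-3.69), AT1G23390 (-3.67) and AT5G19120 (-3.58), with adjusted p from 1.57e-06 to 1.35e-05. Higher at 24 h than at 1 h were also GI (2.53), GSTU25 (2.57), IAA29 (2.26), UGT78D2 (1.68), GH3.3 (1.14, adjusted p = 0.0116) and PRH75 (1.02), and lower were EXPA8 (-2.52), LHCB4.2 (-1.16) and AT5G48570 (-1.53, adjusted p = 0.0226). Of these, GH3.3 was lost without 1 h replicate 1 (adjusted p = 0.0783), 1 h replicate 2 (0.0524) or 24 h replicate 1 (0.0663), and AT5G48570 without 1 h replicate 1 (0.134), 1 h replicate 2 (0.0931) or 24 h replicate 2 (0.128).

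Between 1 h and 24 h, 1701 probe sets rose and 2205 fell. The total of 3906 was 2042 without 1 h replicate 1 and 2396 without 1 h replicate 2. Of the calls 43.5% were higher, but 57.1% (2121 higher, 1594 lower) with equal medians, which moved the median log2 change of all probe sets from -0.08 to 0.04. The 6 COR genes all rose (6 adjusted over the list alone, median 3.99, camera adjusted p = 7.47e-09, and adjusted p = 0.0705 with an estimated correlation). The auxin and growth list gave 2 rises and 1 fall, 2 and 2 adjusted over the list alone (camera adjusted p = 0.398). The photosynthesis list gave 1 fall, 1 adjusted over the list alone (median -0.30, camera adjusted p = 0.217), and a median of -0.41 after quantile normalization (adjusted p = 0.00678). Of the 12 rapid signalling genes 7 fell (median -0.83, adjusted p = 0.00682, but adjusted p = 0.386 with an estimated correlation). RNA processing genes rose (17 of 34, adjusted p = 9.2e-08, but adjusted p = 0.212 with an estimated correlation), and 9 of 13 dehydration-related genes rose and 1 fell (adjusted p = 3.89e-05, but adjusted p = 0.386 with an estimated correlation), where the 7 that are not COR genes had a median of -0.13. Autophagy genes fell (6 of 10, adjusted p = 0.00129, but adjusted p = 0.386 with an estimated correlation), as did 11 of 33 nuclear photosynthesis genes (adjusted p = 0.00707, but adjusted p = 0.393 with an estimated correlation). Of 9 genes of amino acid breakdown 6 fell and 1 rose (median -0.96, adjusted p = 0.0117, but adjusted p = 0.386 with an estimated correlation). These 6 camera calls of annotation lists held with each array left out.

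Whether the 24 h levels persist was asked by comparing 7 days with 24 h, and some cold-induced genes were lower at 7 days. COR47 fell by 1.28 on the log2 scale (limma adjusted p = 0.0173), LTI30 by 1.1 (adjusted p = 0.0355) and TIL by 0.96 (adjusted p = 0.00916), while COR15A and COR15B differed by -0.36 (adjusted p = 0.763) and -0.49 (adjusted p = 0.507). UGT78D2 fell from 594 to 161 (-1.83 ± 0.28, adjusted p = 0.00306) and EXLA2 from 330 to 73.4 (-2.05, adjusted p = 0.000619). AT1G19960 rose from 56.1 to 743 (3.55 ± 0.21, adjusted p = 5.02e-06) and AT5G03350, a lectin-like gene, from 521 to 3590 (2.76 ± 0.25, adjusted p = 0.00018).

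In this step 726 probe sets rose and 670 fell. The total of 1396 was 718 without 24 h replicate 1, 599 without 24 h replicate 2, 291 without 7-day replicate 1, 714 without 7-day replicate 2 and 808 without the filter. Of the 1771 probe sets higher at 24 h than at 0 h, 405 were lower at 7 days than at 24 h and 26 higher still, and 817 were still above 0 h. Of the 2303 that were lower at 24 h, 409 were higher at 7 days than at 24 h, 43 lower still, and 1066 still below 0 h. Both sets were picked by their 24 h arrays, which the comparison with 7 days uses again. Noise on those arrays favours a return towards 0 h, by an amount that was not measured. Other large rises were AT5G52760 (2.67), AT2G37130 (2.65) and AT1G19530 (2.58), and the largest falls AT1G20030 (-3.41), AT2G24560 (-2.78), AT1G51090 (-2.71), AT1G10770 (-2.47) and AT2G22590 (-2.40), with adjusted p from 0.000372 to 0.00716. WRKY53 (1.02, adjusted p = 0.0274) and EXPA8 (1.70, adjusted p = 0.0222) rose, and GH3.3 (-1.20, adjusted p = 0.0238), AT5MAT (-1.16, adjusted p = 0.0394) and PRH75 (-0.82, adjusted p = 0.0284) fell.

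Of the 19 named calls in this step, 9 were lost when an array was left out: COR47, LTI30, TIL, WRKY53, EXPA8, GH3.3, AT5MAT, PRH75 and AT1G10770. Leaving out 24 h replicate 1 ended 5 (adjusted p 0.0751 to 0.126), 24 h replicate 2 ended 7 (0.0537 to 0.216), 7-day replicate 1 ended all 9 (0.0544 to 0.23) and 7-day replicate 2 ended 4 (0.0628 to 0.133). AT5MAT was also lost without 1 h replicate 1 (0.0526) or 1 h replicate 2 (0.0552). Without the filter 7 of them were lost, and without the intensity trend LTI30 (0.0636) and PRH75 (0.0537). Of the 6 COR genes 3 fell (3 adjusted over the list alone, median -0.73, camera adjusted p = 0.00672, but adjusted p = 0.426 with an estimated correlation), and of 4 flavonoid genes 2 fell (2 adjusted over the list alone). The auxin and growth list gave 1 rise and 1 fall, the same adjusted over the list alone (camera adjusted p = 0.673), and the photosynthesis list 0 of 6, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.488). Dehydration-related genes were lower at 7 days (4 of 13 fell, 3 of them COR genes, median -0.51, adjusted p = 0.0051, but adjusted p = 0.601 with an estimated correlation, and 0.06 without 7-day replicate 2). Chloroplast genes of the photosynthetic complexes were lower (1 of 33 fell, median -0.33, adjusted p = 0.0214, but adjusted p = 0.616 with an estimated correlation, and 0.167 without 24 h replicate 1). Genes of autophagy (median 0.50, adjusted p = 0.0354, and adjusted p = 0.611 with an estimated correlation) and amino acid breakdown (median 0.42, adjusted p = 0.0372, and adjusted p = 0.601 with an estimated correlation) were higher, with 1 called gene each. Without 24 h replicate 2 both were lost (adjusted p = 0.347, with a median of 0.29, and 0.203), and without 7-day replicate 1 the breakdown list (0.0762), whose median was 0.71 without 24 h replicate 1. Among RNA processing genes ATL5 fell by 1.64 and AtRZ-1c, a glycine-rich RNA-binding protein gene, by 1.66, while the list of 34 did not pass (camera adjusted p = 0.095, and 0.0473 without 7-day replicate 2).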

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

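Both results here were picked out after the calls were seen, because calls went in opposite directions, so the p-values between cold times given here follow in part from that choice and are no independent test of a difference. At 1 h 10 probe sets were higher than at 0 h, and at 24 h they were lower than at 0 h. Of these, 3 stand for a single gene: AT2G20670 (log2 fold change 1.79 at 1 h and -1.08 at 24 h, adjusted p between the times 3.12e-05), AT1G76600 (1.56 and -0.64, adjusted p = 3.66e-05) and TET8, a tetraspanin gene (1.04 and -0.75, adjusted p = 4.59e-05). The 1 h calls of AT2G20670 and AT1G76600 are among the 7 that were lost when an array was left out.

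At 24 h and 7 days 22 probe sets changed in opposite directions against 0 h, 16 lower and then higher and 6 higher and then lower. Of the 16, the single genes were AT1G19960 (-1.60 and 1.95, adjusted p between the times 5.02e-06), AT5G24210 (-1.61 and 0.87, adjusted p = 0.000197), AT1G21520 (-1.23 and 0.89, adjusted p = 0.000931), AT2G41090, a calmodulin-like gene (-0.69 and 1.04, adjusted p = 0.00128), AT3G60420 (-1.19 and 1.12, adjusted p = 0.00207) and AT5G39670 (-0.87 and 0.90, adjusted p = 0.00404). Of the 6, they were AT1G20030 (2.00 and -1.40, adjusted p = 0.000655), AT5G35970 (0.69 and -0.81, adjusted p = 0.0012) and AT3G22620 (0.79 and -0.82, adjusted p = 0.00453). These counts were not recomputed under other processing, and plants at 7 days were also older.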

How the results depend on the processing

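Leaving out arrays for the overlaps, every alternative for the lists drawn from the annotation, and those for list members were chosen after seeing the data. Of 117 results of named genes, 112 passed the test. Of these, 98 did not lose the call under any alternative that uses all arrays of the groups compared, and fewer with each array left out as well. Results that the stricter filter removed count as kept here, since it held 103 of the 117 results. Of their 2092 values 1989 kept direction and call, 99 kept direction and lost the call, 0 reversed, and 4 uncalled values differed in sign. With an array left out the counts ranged from 16 to 57 at 1 h, 2694 to 3942 at 24 h, 1472 to 3202 at 7 days, 2042 to 3840 for 24 h against 1 h, and 291 to 1354 for 7 days against 24 h. The overlaps ranged from 8 to 18 (1 h and 24 h), 5 to 15 (1 h and 7 days) and 1023 to 1726 (24 h and 7 days). The fixed lists past the threshold numbered 0 to 1 at 1 h and 1 to 2 at 24 h. These fits have fewer arrays. Asking for at least 2-fold, which can only shorten a list, left 2099 at 24 h, 1472 at 7 days, 2069 for 24 h against 1 h, 699 for 7 days against 24 h, and overlaps of 7 (1 h and 7 days) and 832 (24 h and 7 days). Without the filter, which adds probe sets to the adjustment, the counts were 23 at 1 h and 808 for 7 days against 24 h, and without the intensity trend 29 at 1 h; the cause was not tested. After quantile normalization 2 fixed lists passed at 24 h, at 7 days and for 24 h against 1 h, where photosynthesis joined the COR genes, and the cause was not tested. Camera could test only these 2 fixed lists and the auxin and growth list. With an estimated correlation 0 passed in the 4 comparisons where the COR list had passed.

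The replicate number as a block gave counts of 55 at 1 h, 4391 at 24 h, 3328 at 7 days, 4188 for 24 h against 1 h, 1644 for 7 days against 24 h, and 5356 at any time, and changed no call of a named gene or fixed list. Of the lists drawn from the annotation, the UDP-glycosyltransferase list lost its call at 7 days with the block (adjusted p = 0.0521) and gained one for 7 days against 24 h (adjusted p = 0.045). The gain was not particular to the block. It also occurred with a pseudocount of 24 (camera adjusted p = 0.0425), without the filter (camera adjusted p = 0.0366) and with some of the arrays left out. Deviations of same-numbered arrays correlated at 0.385 (0 h and 1 h), 0.403 (0 h and 24 h), 0.243 (1 h and 24 h), -0.209 (0 h and 7 days), -0.026 (1 h and 7 days) and -0.166 (24 h and 7 days), that is, above 0.1 among 0 h, 1 h and 24 h and below 0 for each pair with 7 days. The labels do not say what the numbers share, and the samples were not treated as paired. The promoter motif search and its alternative with a longer promoter were not run. Dim genes limit the arrays, since the pseudocount of 8 shrinks their changes. Separately, 48.9% of simulated log2 changes of 1 were recovered, in probe sets picked at any brightness and changed on the log2(signal + 8) scale. That simulation changed 200 of 15017 probe sets, where 27.1% were called at 24 h, so its recovery need not hold there.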

Other observations

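All tests here were chosen after the result was seen, except that of the array scaling for chloroplast transcripts. The root list was widened from 3 genes (median -0.19), and its error was changed from 0.1 to the spread between genes, after results had been seen, and the brighter root genes were set apart later still. Some cell wall, sugar transport and protein folding genes were called, although none of these 4 lists passed as a group at 24 h, and the members were named after their values were seen. At 24 h 6 of 21 expansin and xyloglucan-modifying genes rose and 5 fell (camera adjusted p = 0.411), with XTH20 at a log2 fold change of 3.18 and EXPB3 at -1.23. Among wall synthesis genes 4 of 30 fell (adjusted p = 0.512), including the endoglucanase-like gene GH9B13 (-2.73) and CSLA03, a glucomannan synthase-like gene (-1.74). Of 19 starch and sugar genes 5 rose and 2 fell (adjusted p = 0.263), with the sugar transporter genes SWEET13 at 2.36, TMT2 at 1.58 and SWEET17 at -1.23. Of 11 cytosolic folding genes 7 rose and 1 fell (adjusted p = 0.104), among them Hop2 (1.38). At 7 days SWEET13 was at 2.09, SWEET17 at -1.82 and GH9B13 at -1.62. The members named here kept their calls with each array left out, which was a condition for naming members of these lists and so is no further support.

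Chloroplast-encoded transcripts were higher at 1 h by a mean of 0.71 on the log2 scale, with 66 of 68 genes higher, 0 called and 36 at an unadjusted p under 0.05. The scaling of the arrays is argued against, since 526 nuclear probe sets of the same brightness had a median change of -0.05. A larger share of green tissue as the whole cause is argued against as well. The 33 nuclear-encoded photosynthesis genes had a median of 0.08, a value already known when that test was added. Its error of 0.03 comes from the spread between genes on the same arrays and leaves out the spread between arrays. Without 0 h replicate 2 this median was 0.16. However, 13 root genes had a median of -0.56 at 1 h (12 lower, 0 called), the direction that a larger green share would give, so some part of it stays open. RNA quality or labelling cannot be told apart from an effect of cold: the actin ratio predicts 0.15 ± 0.12 of the 0.71, and in 3 of 4 groups the array with the higher ratio had the higher chloroplast mean. A response of chloroplast transcripts to cold or to dim light may also contribute and was not tested.

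Arrays with the same number deviated together from their group means at 0 h, 1 h and 24 h. RNA quality or labelling as the cause cannot be told apart from others, since its controls differ. The signs of 6 of 6 correlations follow from which array of each pair has the higher actin ratio. From ubiquitin 6 follow, but from GAPDH 2, and these signs are not independent. The ubiquitin ratios of the 0 h arrays were nearly equal (2.3 and 2.28), so its signs for pairs with 0 h rest on a slight difference. The scaling of the arrays stays open, since removing the trend with brightness hardly moved r for 0 h and 24 h (0.403 before, 0.399 after) and so decides nothing. No biological explanation was tested.

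PYK10, NAI1, NAI2 and the jacalin-related genes JAL22, JAL33 and JAL34, which belong to the endoplasmic reticulum body system, fell at both 24 h and 7 days (6 of 6 each, medians -1.71 ± 0.32 and -1.38). The group was assembled after values had been seen, so 6 of 6 follows in part from that choice: over all probe sets 2303 of 15017 fell at 24 h, and the jasmonate and defence list that holds the 3 jacalin genes did not pass (3 of 10 fell at each time, adjusted p = 0.263 and 0.27). The calls of JAL22 and JAL33 held with each array left out, those of PYK10 at 24 h and of JAL34 did not (JAL34 was lost without 2 of the arrays at each time, up to adjusted p = 0.0833 at 24 h without 24 h replicate 2 and 0.0908 at 7 days without 7-day replicate 2), and NAI1 and NAI2 were not tested in this way. For these 6 genes, plant age as the whole cause is argued against by the fall of -1.71 at 24 h. They were picked after their values had been seen, which favours such a fall, so this is no independent test. A lower share of root RNA cannot be told apart from a response to cold or dim light. The 13 root genes (median signal 53.9 at 0 h) had a median of -0.56 at 1 h (12 lower, 0 called, 4 at an unadjusted p under 0.05). Their median was -0.35 at 24 h (3 fell) and -0.20 ± 0.20 at 7 days (2 fell). The 6 brighter ones were at -0.91 at 24 h and -0.66 ± 0.29 at 7 days. The latter is near the -0.69 that was set as the least change a root share would need. These 6 were picked by their signal on the 0 h arrays, the baseline of their change, so noise on those arrays favours a fall. The errors of the medians given here come from the spread between genes on the same arrays and leave out the spread between arrays.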
